A study of Zea mays with 54 samples.

How the data were processed

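Roots of 9 maize (Zea mays) genotypes grown at high or low phosphate (P) supply were profiled by RNA sequencing, with 3 replicates in each of 18 groups and 54 libraries in all. Total RNA was extracted with a column kit for plant RNA and made into libraries with an NEBNext Ultra RNA kit, per the labels' protocols. The labels do not say whether a replicate was a single plant or a pool, so the p-values measure only the spread between these samples, which may be technical. The authors' raw read counts per gene were deposited in 2 count tables, 1 with 36 libraries of 6 genotypes (EP1, F2, F160, F142, SF1, SM1) and 1 with 18 libraries of 3 genotypes (P024, F7, P415). Reads were processed with fastp, HISAT2 and HTSeq on the B73 RefGen_v4 build, per the submitters' processing notes; versions and strand settings are not given in the sources used here. Both tables list the same 46430 features. The authors also deposited 2 tables of FPKM values. Each FPKM above 0 equalled its count scaled by gene length and library total within a relative tolerance of 0.001, in 1067424 of 1067424 values of the first table and 515741 of 515741 of the second, so FPKM entered no test.

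Of the features, 44146 were nuclear gene models, and 0 of these IDs matched an entry of the RefSeq gene table of the B73 NAM-5.0 assembly, which carries other identifiers. The files do not pair the nuclear IDs with names. All 365 organelle IDs matched a locus tag and are named by its symbol. Of 42 gene lists fixed before the data were examined, 2 matched any organelle symbol and the best filled had 4 tested features, under the minimum of 5, so the gene list tests and the cell type marker lists could not be run. Overlapping genes and near-identical copies cannot be separated here, because counting was done upstream.

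Library totals ran from 15585904 to 28733284 counts in the first table and from 15830403 to 24821387 in the second. A count of 0 in the shallowest library allows up to 0.192 CPM (counts scaled to a common library total), taking 3 counts as the limit; limits and intervals cover counting error only. All 54 pairs of replicates within groups differed by more than sampling noise, with a lowest chi-square of 7.02 per degree of freedom over genes with at least 20 counts, so none was merged.

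Low P was compared with high P within each genotype with edgeR's quasi-likelihood F-test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the deposited counts, after TMM scaling and filterByExpr, with Benjamini-Hochberg adjustment and a threshold of 0.05. A joint model of all 54 libraries, with a mean for each genotype and P level, gave the response averaged over the 9 genotypes, the genotype by P interaction over all 9 responses, and each genotype's response against the mean of the other 8. Low P against high P lies within a genotype and within a count table. The interaction and the comparisons with the other 8 genotypes span both tables and carry any difference between them in the size of the response. With 3 libraries on each side an exact permutation test of a single gene cannot go below 0.10, and the calls rest on the spread shared across genes. The SE printed beside an edgeR log2 fold change is the absolute log2 fold change over the square root of the F statistic. It was not estimated by the model and is approximate. The median log2 fold change of tested genes lay near 0 under TMM; under scaling by total counts it reached -0.105 in F160 and -0.104 in SF1, and changes are given relative to TMM.

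The models were tested on simulated counts, with 200 changed genes in each genotype comparison. In the joint model 100 genes changed in all genotypes and another 100 in 1 genotype alone. For 2-fold and 4-fold changes the share recovered was 78% and 98% in the SF1 comparison (25012 genes), 66% and 96% in EP1 (24904 genes), 25% and 81% in SM1 (24658 genes), 0% and 41% in F7 (24123 genes), 2% and 52% in P415 (23636 genes), and 0% and 0% in P024 (23394 genes). False calls made up 9.5% of the simulated calls in EP1, 6.87% in F2, 4.9% in F160, 6.78% in F142, 9.28% in SF1, 10.2% in SM1, 12.8% in F7, 3.57% in P415 and 7.02% for the average response, above the nominal 5% in most, and 3.06% for the interaction. In the simulated joint model the average response recovered 100% of 2-fold changes and the interaction 95% of genes changed by 4-fold in 1 genotype, with 29407 genes. Its spread was set alike in all genotypes, while the real biological coefficient of variation ran from 0.14 (SF1) to 0.599 (P024). Recovery and false calls of the joint model on the real data may therefore be worse.

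Genes were to be named by a rule fixed before the data were examined: for the average response the largest changes past the threshold with the same sign in all 9 genotypes, for each genotype the 3 largest rises and falls with no overlap of the low P and high P libraries, for the interaction the 8 named genes and for each genotype against the others the 2 named genes with the smallest p, all with a mean log2 CPM of at least 1 and a known name. Because nuclear IDs carry no name, the rule reached only organelle rRNA genes. The 2 largest rises and 2 largest falls of the average response by the same rule without the name are printed as IDs, and other organelle genes were chosen after their values were seen. Organelle levels were also compared as log2(CPM + 0.5) with a two-sided permutation test that reassigned P labels within genotypes 100000 times, adjusted over 6 measures.

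Whether replicate numbers pair the high P and low P libraries was checked from the correlation of their deviations from group means. It exceeded 0.1 for every number in F160 (lowest 0.101), P024 (lowest 0.501) and P415 (lowest 0.162), and not in the other 6 genotypes. In P024 and P415 not every library correlated best with its own number, so the pairs are not established there. The labels do not say what a number marks. Chance was checked for the average response with P labels reassigned within genotypes. That largely removes the response of a genotype unless a draw keeps or mirrors its real split, so it does not test equal responses of the genotypes. For the interaction and each genotype against the other 8, the residuals around genotype means and 1 common low P effect were therefore reassigned within genotypes in 100 draws, the real one included, with limma-trend on log2 CPM. These draws were added after those of the P labels had been seen for the same comparisons. The residuals hold each genotype's own deviation from the common effect, so a draw can restore or mirror it. Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE scaling, no filter on low counts, the joint model, a replicate block, a fold threshold, limma-voom, each count table alone and each library or replicate number left out. Leaving out the libraries that stood apart together, or from anything but the fit of their own genotype, was added after the data were seen. The replicate number was a block within genotype in the joint model.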

Results

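Root transcriptomes of 9 maize genotypes at high and low phosphate supply were compared to ask which genes respond to phosphate limitation and how far genotypes with different breeding histories differ in that response. Each genotype had 3 high P and 3 low P libraries. The genotypes EP1, F2, F160, F142, SF1 and SM1 were in the first count table, with mean totals of 19282524 counts at high P and 22229094 at low P, and P024, F7 and P415 in the second, with 18488036 and 17876084. Nuclear gene models took a median of 99.9% of the counts and mitochondrial genes 0.0311%. The labels do not give the breeding class of a genotype, so classes were not compared.

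Averaged over the 9 genotypes, low P changed 11492 of 29705 tested genes, of which 5993 were higher and 5499 lower than at high P (edgeR quasi-likelihood test, adjusted p under 0.05). Changes of at least 2-fold were found for 1502 higher and 1033 lower genes. Of the called genes, 1339 were higher and 530 lower with the same sign in all 9 genotypes. The excess of rises is not firm: falls outnumbered them with RLE scaling (5510 higher, 6120 lower), limma-voom (6164 and 6301), without replicate 2 (4663 and 4880) and without P024, F7 low P 2 and F7 high P 1 (7125 and 7443). The first count table alone gave 17115 calls, 8360 higher and 8755 lower, and the second alone 1167.

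The largest rise was that of Zm00001d005742, whose average log2 fold change was 9.44 ± 0.35 (SE) with an adjusted p of 3.8e-23. It stood at 140 ± 3.03 CPM (SD, n = 3) at low P in EP1 and at 0.157 ± 0.185 CPM at high P, and was called in 8 of the 9 genotypes. In F142 it was at 0 in all high P libraries and at 120 ± 6.93 CPM at low P, at least 2320-fold higher against a floor of 3 counts over the high P group. In P024, the remaining genotype, it averaged 5.69 ± 5.53 CPM at high P and 32.1 ± 31.3 CPM at low P. Zm00001d029085 followed, with an average log2 fold change of 8.98 ± 0.34 (SE) and an adjusted p of 8.21e-20. It was at 0 in all high P libraries of F2, F142, SF1 and SM1, and rose to 48.4 ± 4.12, 105 ± 16.3, 59.4 ± 15.6 and 41.5 ± 13.7 CPM at low P. Those rises were at least 867-fold, 2030-fold, 1190-fold and 900-fold. In EP1 the same gene reached 0.455 ± 0.0786 CPM. In the second count table it went from 1.43 ± 1.24 to 10.7 ± 4.82 CPM in P024, from 0.41 ± 0.342 to 4.92 ± 2.12 CPM in F7 and from 0.053 ± 0.0918 to 3.38 ± 0.589 CPM in P415, of which the difference in F7 passed the threshold. The average log2 fold change of Zm00001d005742 was 11.12 in the first count table alone and 6.13 in the second, and that of Zm00001d029085 was 11.52 and 4.08. A fitted fold of a gene at 0 in a group depends on the model's prior count.

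**Figure D1:**
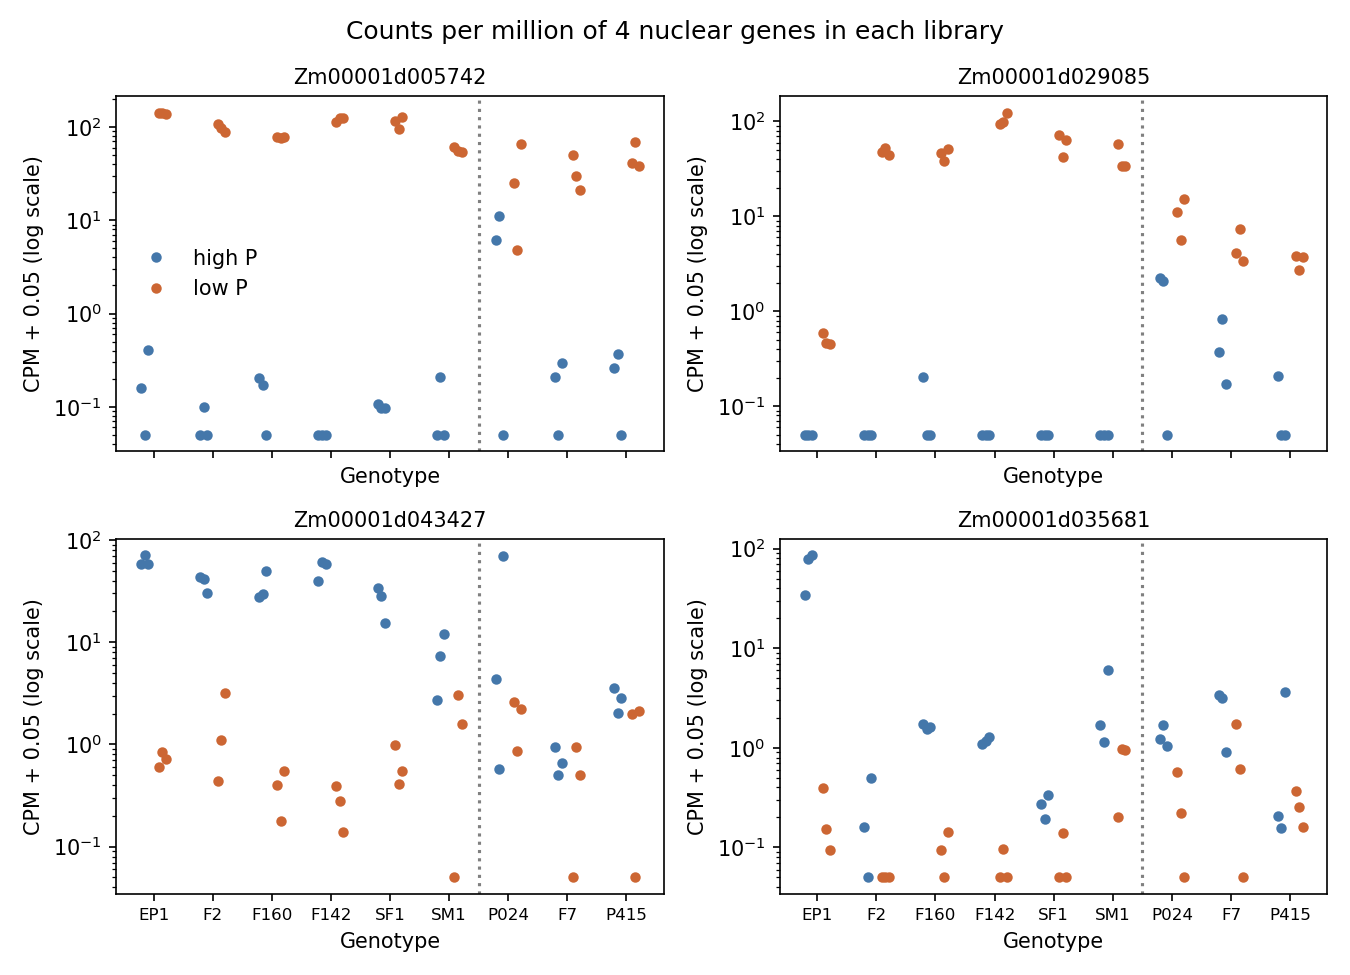
Expression in CPM (plus 0.05, log axis) of 2 genes that rose and 2 that fell, with a point for each of the 3 libraries per genotype at high P (blue) and low P (orange); the dotted line separates the 2 count tables. Zm00001d005742 averaged 140 CPM at low P in EP1 and 0.157 CPM at high P.

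The largest fall was that of Zm00001d043427, with an average log2 fold change of -4.23 ± 0.35 (SE) and an adjusted p of 3.21e-13. Its level in EP1 went from 62.2 ± 7.34 CPM at high P to 0.671 ± 0.128 CPM at low P (SD, n = 3), and in F142 from 53.0 ± 11.8 to 0.219 ± 0.125 CPM. In F7 it was at 0.648 ± 0.221 CPM at high P and 0.447 ± 0.442 CPM at low P, with an adjusted p of 0.739. Zm00001d035681 had an average log2 fold change of -3.88 ± 0.45 (SE) and an adjusted p of 4.64e-09. It fell in EP1 from 66.0 ± 28.1 to 0.165 ± 0.16 CPM and in F160 from 1.58 ± 0.0864 to 0.045 ± 0.0458 CPM, and was called in 3 genotypes in all, F142 being the third. In the 8 genotypes other than EP1 its high P mean was between 0.187 and 2.90 CPM. In the second count table alone neither fall passed the threshold, with log2 fold changes of -1.71 and -2.16 and adjusted p of 0.282 and 0.155 in edgeR.

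The plastid gene matK, which encodes the maturase inside the intron of trnK, was higher at low P in 9 of 9 genotypes. Its log2(CPM + 0.5) rose by 0.72 on average (SD 0.48 over genotypes), with a permutation p of 1e-05, the smallest these permutations can give, and an adjusted p of 6e-05. The size depended on the offset, with 1.37 at 0.1 CPM and 0.48 at 1 CPM, and was 2.33 ± 0.34 (SE) in the joint edgeR model. In SF1 it went from 0.167 ± 0.0229 to 1.33 ± 0.611 CPM and in F2 from 0.935 ± 0.199 to 2.18 ± 0.447 CPM (SD, n = 3). It rose within the genotype in EP1, F2, F142 and SF1, with edgeR adjusted p of 0.00282, 0.0189, 0.000715 and 0.00122. It was low in every library, and in the second count table alone the difference was 0.19 with a permutation p of 0.205.

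Of 23 mitochondrial features tested, 6 rose on average at low P, 0 fell and 17 did not pass the test. They were cox2, a subunit of cytochrome c oxidase (log2 fold change 1.06 ± 0.27, SE, adjusted p 0.0016), the ribosomal protein genes rps12 (0.44 ± 0.17, adjusted p 0.0383) and rps2B (0.54 ± 0.18, adjusted p 0.0144), the open reading frames orf147-b and orf101-a (1.30 ± 0.23 and 0.51 ± 0.19, adjusted p 1.38e-05 and 0.0316), and the small rRNA gene rrn18 (0.38 ± 0.14, adjusted p 0.0328), all in edgeR. These features were singled out after their values were seen, and all but rrn18 were low, with a mean log2 CPM from -1.47 in cox2 to 0.30 in orf101-a. For each of the 6 the largest fitted rise was in P024 or P415, as in orf147-b (3.45 and 4.58), cox2 (2.56 and 2.04) and rps2B (1.84 and 1.48). The averages thus lean in part on these genotypes, whose replicates spread widely (below). In the joint model rps12 was higher in 5 of 9 genotypes, orf147-b and orf101-a in 6, and cox2, rps2B and rrn18 in 7. On the log2(CPM + 0.5) scale rrn18 was 0.24 higher at low P with a permutation p of 0.103. By genotype, 5 of 18 tested mitochondrial features rose in SM1 and 0 fell, 3 rose and 2 fell of 13 in SF1, 1 rose and 2 fell of 16 in F2, 1 rose and 1 fell of 8 in EP1, 1 rose and 0 fell of 9 in F142, and 0 were called in F160, P024, F7 or P415. The library labelled F7 low P 2, which carried P024 transcripts (below), had rrn26 at 304 CPM against 1280 and 847 CPM in the other F7 low P libraries, and rrn18 at 49.3 against 190 and 145 CPM. Without it 1 of 18 mitochondrial features rose in F7 and 0 fell, and 10 of 25 rose on average and 0 fell, with all 6 of the above among them. By the fixed rule, rrn26, the large rRNA gene, fell in EP1 from 267 ± 27.2 to 198 ± 20.5 CPM (log2 fold change -0.43 ± 0.13, SE, edgeR adjusted p 0.0255), and rrn18 rose in SM1 from 67.0 ± 14.9 to 98.3 ± 11.8 CPM (0.66 ± 0.15, adjusted p 0.0184).

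Within genotypes of the first count table, SF1 changed most genes at low P, with 7102 higher and 6770 lower of 25283 tested. F142 followed with 6514 higher and 6189 lower, EP1 with 5300 and 5453, SM1 with 4311 and 3902, F2 with 4032 and 3557, and F160 with 3325 and 2376. Restricted to changes of at least 2-fold, the genotypes had 5517 calls in SF1, 5028 in F142, 4509 in SM1, 4243 in EP1, 4001 in F2 and 2788 in F160. The order also depends on the replicate spread of each genotype. With the spread shared in the joint model, calls were 6939 in SF1, 6535 in SM1, 6254 in F142, 4850 in F2, 4533 in EP1 and 2478 in F160. Counts fell by more than 1.5 times without the library F2 low P 1 (4607 calls), SM1 low P 2 (4826 calls), and F160 high P 1, high P 2 or low P 1 (3659, 3333 and 3352 calls).

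**Figure D2:**
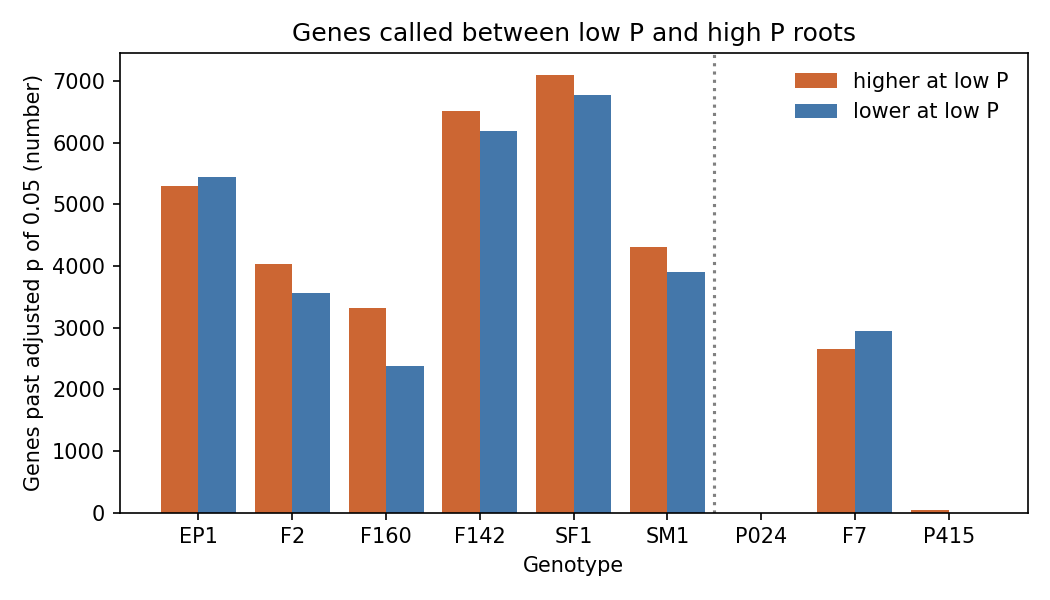
Number of genes called higher (orange) and lower (blue) at low P than at high P in each genotype by edgeR at an adjusted p under 0.05; the dotted line separates the 2 count tables. The bars reach 7102 and 6770 genes in SF1, and P024 has 0.

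In the second count table, F7 changed 2660 genes upward and 2951 downward at low P, P415 changed 49 genes, all higher, and P024 changed 0. For P415, DESeq2 called 272 genes higher and 51 lower, and the joint model 284 higher and 33 lower. The joint model called 5789 genes higher and 4950 lower in F7, and 32 and 15 in P024, a count of 47 that became 100 when the library labelled F7 low P 2 was left out of the model. For P024, edgeR called 0 of 23864 genes with 269 at an unadjusted p under 0.05, and DESeq2 called 1 with 571 at an unadjusted p under 0.05. The P024 comparison recovered 0% of simulated 4-fold changes, so its 0 calls do not show that its genes were unchanged. The spread between replicates was wider here, with a biological coefficient of variation of 0.599 in P024, 0.372 in F7 and 0.337 in P415 against 0.14 (SF1) to 0.241 (SM1) in the first table. P415 had 1, 2 or 2 calls without its high P library 1, 2 or 3 and 15 without low P 3, while F7 had 3491, 2567 and 3068 calls without high P 1, 2 or 3 and 3709 without low P 3.

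The library labelled F7 low P 2 carried transcripts of another genotype. All 33 genes expressed at 5 CPM or more in every P024 library and under 0.2 CPM in the other F7 libraries were over 1 CPM there, at a median of 0.913 of their P024 level (quartiles 0.805 and 1.02). The 108 genes with the opposite pattern, expressed in F7 and silent in P024, stood at a median of 0.249 of their level in the other F7 libraries (quartiles 0.177 and 0.307). By these ratios P024 RNA was likely the larger part of the library, which was kept under its F7 label in the reported fits. Without this library F7 had 8395 calls in place of 5611, and 5482 genes were called in both fits, all 5482 in the same direction. The library labelled F7 high P 1 also held transcripts of genes silent in the other F7 libraries (F7 low P 2 not counted), at lower levels. Of such genes expressed in another genotype, 21.4% to 37.5% were over 1 CPM there, depending on the genotype. Their median was 0.00413 to 0.0257 of their level in that genotype. These shares do not identify a source, and a mixture was not tested for this library. In the libraries other than these 2 the highest such share was 4.35%. Without both F7 libraries the count was 7880.

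**Figure D3:**
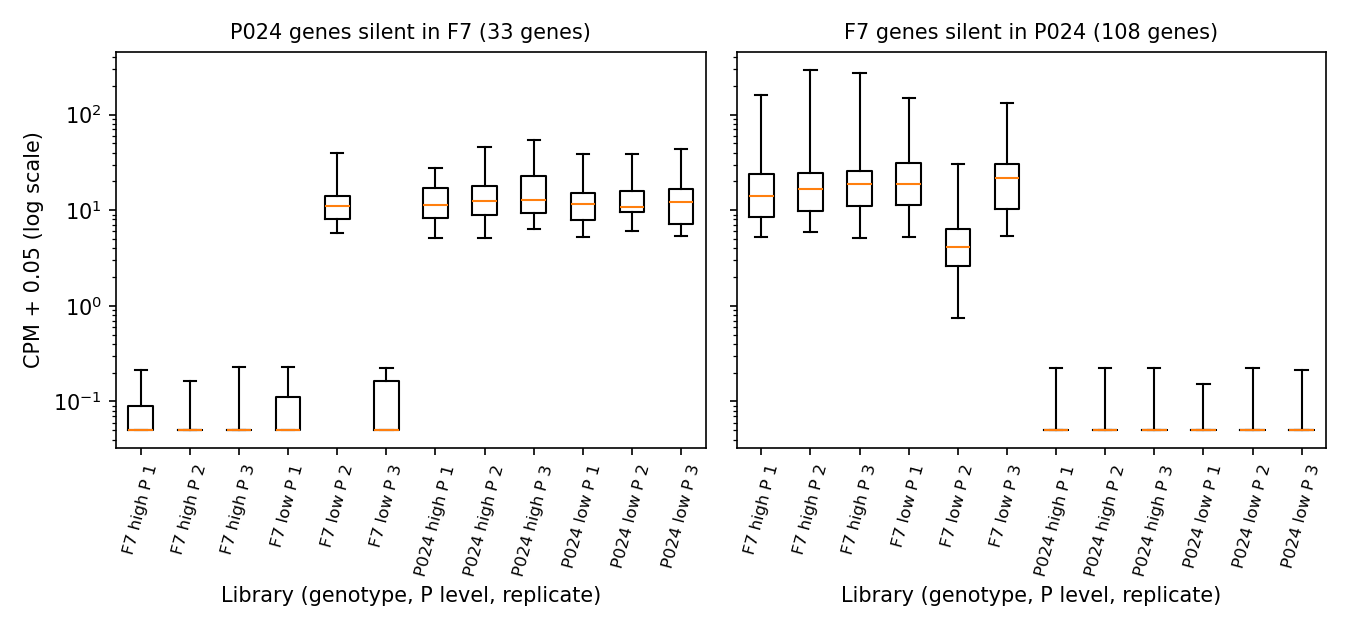
Expression in CPM (plus 0.05, log axis) in each F7 and P024 library of 33 genes expressed in P024 and silent in the other F7 libraries (left) and of 108 genes expressed in F7 and silent in P024 (right). Boxes span the quartiles with the median line and whiskers reach the extremes; the library labelled F7 low P 2 holds both sets, at medians of 0.913 and 0.249 of their level in the genotype of origin.

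The genotype by P interaction of the joint edgeR model called 12556 of 29705 genes (42.3%). Of these, 7083 were also among the genes called in the average response. With residuals reassigned around 1 common response, limma-trend still gave up to 9512 interaction calls, against 13252 in the real draw. The residuals hold each genotype's own deviation, and a draw can restore or mirror its split by P level. The highest counts may therefore hold real differences. The draws neither show how many calls are false nor test a single call. Against the mean of the other 8 genotypes, F7 differed for 9734 genes, SM1 for 2092, SF1 for 1899, F142 for 1574, EP1 for 1513, P024 for 1449, F2 for 1443, P415 for 710 and F160 for 267. Reassigned residuals gave up to 9783 calls for F7, against 10817 in the real draw. For P024 40 of 100 reassignments of residuals gave at least as many calls, so chance is not excluded over all draws. Its same-numbered libraries correlated above 0.1, but not each best with its own number, so the pairs are not established. Of the 38 draws that part all 3 such pairs only the real one reached its count (1709 calls, highest other 690). This does not settle the question. Without the library labelled F7 low P 2 the F7 count was 9802, with 8054 genes in both. The named rRNA genes rrn18 and rrn26 did not pass the interaction test, with adjusted p of 0.454 and 0.528 in edgeR. The interaction count fell to 4320 without replicate 1 of all groups and to 7309 without replicate 2, and was 748 in the second count table alone.

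Over 20802 genes tested in every genotype, 17871 were called in at least 1. In at least 5 genotypes 1805 genes were called higher and 1115 lower, in at least 7 genotypes 366 and 41, in 8 genotypes 42 and 0, and in 9 genotypes 0, as P024 had 0 calls. Of the 17871 genes, 4207 were called higher in some genotypes and lower in others. The responses of SF1 and SM1 were most alike, with a correlation of log2 fold changes across genes of 0.812, followed by EP1 and F2 with 0.793; genes are not independent replicates. SF1 and SM1 shared 3033 higher and 2463 lower genes, where independent lists would share 1090 and 796, and 89 genes went opposite ways against 1870. EP1 and F7 shared 684 higher and 571 lower genes against 510 and 553, and 1466 genes went opposite ways against 1060, with a correlation of 0.046. Without the library labelled F7 low P 2, F7 and EP1 had 2389 genes in opposite and 1876 in the same direction, and a correlation of 0.0539. Opposite calls also outnumbered the same ones with F142 (2612 and 1988), but not with SF1 (1679 and 3298), SM1 (1006 and 2161), F160 (782 and 1782) or F2 (1537 and 1714). Of the 49 P415 calls, 47 were tested throughout and also higher in EP1.

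A response score was defined after the data were seen: the mean log2 CPM of genes called higher minus that of genes called lower in at least 5 of the other 8 genotypes. It rose at low P by 3.85 in SF1, 3.77 in F142, 3.03 in SM1, 3.00 in EP1, 2.83 in F2 and 1.99 in F160, with no overlap between P levels. In the second count table it rose by 0.86 in F7 and 0.73 in P415, also without overlap, and by 0.39 in P024, where the P levels overlapped (high P mean -1.09 ± 0.705, low P mean -0.697 ± 1.3, SD, n = 3). The score genes differed between genotypes, with 1200 to 1508 higher genes in the first table and 1840 to 2007 in the second. On the same genes, called one way in at least 4 of the 5 other genotypes of the first table, the rise was 1.60 to 3.28 in the first table and 0.29 to 0.95 in the second. With 3 libraries against 3, no overlap arises by chance in 0.10 of cases.

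**Figure D4:**
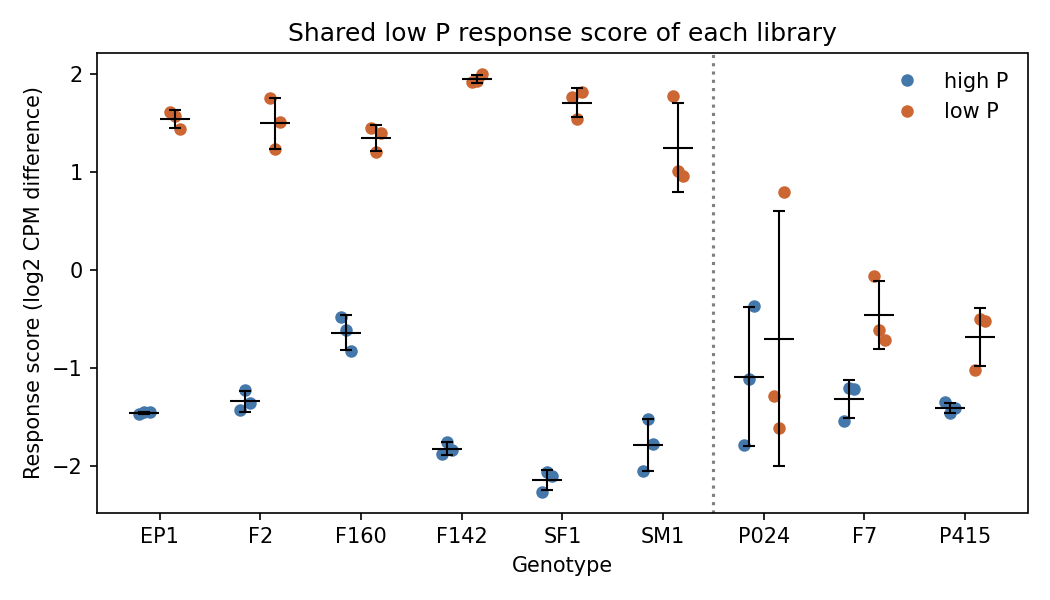
Response score of each library by genotype at high P (blue) and low P (orange), as a difference of mean log2 CPM; points are the 3 libraries, bars show the mean and SD, and the dotted line separates the 2 count tables. SF1 rose by 3.85 and P024 by 0.39.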

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

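The tests of the library labelled F7 low P 2, of the P024 libraries numbered 3, of the split between count tables (other than the thinned counts with the score as reported and the genes called in P415) and of the splits of P024, the reassigned residuals of the joint model, the comparison with draws that part all pairs, and the use of quartiles to read the test on genes called in P415, were chosen only after the results were seen; leaving doubted libraries out together, or from anything but the fit of their own genotype, was also added then.

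A test of the difference in response between genotypes called 12556 genes over all 9. Against the mean of the other 8 it called 9734 genes in F7, 2092 in SM1, 1899 in SF1, 1574 in F142, 1513 in EP1, 1449 in P024, 1443 in F2, 710 in P415 and 267 in F160. Residuals reassigned around a common response still gave up to 9512 interaction calls and 9783 for F7 (limma-trend). Such draws can restore a genotype's own deviation, so they do not show how many calls are false. The counts above are still not counts of proven differences. For P024 chance is not excluded over all draws (40 of 100). Of the 38 that part its same-numbered libraries only the real one reached its count, but these pairs are not established. Among printed genes the interaction had adjusted p (edgeR) of 4.99e-06 for Zm00001d005742, 2.18e-07 for Zm00001d029085, 0.000532 for Zm00001d043427 and 0.0032 for Zm00001d035681. Of the organelle features it passed for orf147-b (0.000473), rrn16-ct (0.0181), cox3 (0.0195), rps2B (0.0244), rps1 (0.0365) and ZemaCr119 (0.0437), all with a mean log2 CPM under 0. For orf147-b the fitted response ran from -0.84 in F7 to 4.58 in P415.

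P024 transcripts in the library labelled F7 low P 2 may come from P024 RNA mixed into an F7 library: 33 P024 genes stood at a median of 0.913 of their P024 level while 108 F7 genes fell to a median of 0.249. P024 RNA would then be the larger part. A swap of whole libraries would leave those F7 genes near 0 and put F7 genes into a P024 library, where at most 0.901% of such genes were over 1 CPM. A response of F7 itself would show in the other low P libraries, where at most 2.63% of 38 P024 genes silent in the high P libraries were over 1 CPM, against 100% in this library. F7 RNA mixed into a P024 library would give the same values and stays open, and no biological explanation beyond the F7 response was tested.

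By the response score the shared response was smaller in all 3 genotypes of the second count table, with mean score rises of 0.657 ± 0.24 against 3.08 ± 0.682 (SD over 3 and 6 genotypes), and on the same genes each first-table genotype rose by at least 0.952 more than the highest of the second. After thinning every library to 15585904 counts the lowest rise of the first table was 1.97 and the highest of the second 0.846, with a smallest gap of 0.947 on the same genes. The score is scaled for depth and its genes were fixed before thinning, so it could hardly change. Counts of calls depend on depth more: thinned first-table genotypes kept at least 5536, against 49 in P415, 0 in P024 and 5611 in F7 without thinning. Depth is thus argued against for the few calls of P415 and P024 only. Replicate spread is argued against for F7 and P415, which lay 4.08 and 4.37 standard errors below the lowest first-table genotype, F160, on the same genes with libraries paired where the numbers pair them (4.00 and 5.08 without pairs), while P024 lay 2.61 below it with pairs and 1.34 without, so its wide spread stays open. On the 49 genes called in P415 the lowest first-table median exceeded that of P415 by 0.332, less than the spread of the per-gene difference (quartiles -0.393 and 1.63), and the medians were 3.64 in F7 and 1.58 in P024, neither used to pick them, against 3.7 in F160 and 3.98 to 5.28 in the other first-table genotypes, so the choice of score genes stays open. Genotype and a separate preparation of the second table's libraries cannot be told apart, because no genotype is in both tables.

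The P024 libraries numbered 3 stood apart at both P levels: 8595 genes at high P and 10231 at low P were over 2-fold from libraries 1 and 2, against a median of 405.5 and at most 2697 in the 16 groups of the other genotypes. RNA of the other 8 genotypes is argued against. At most 3.4% of genes expressed in any of them and silent in the other P024 libraries were over 1 CPM. RNA of a genotype outside these was not tested. Gene length bias is argued against as well, with correlations of -0.0215 at high P and 0.0205 at low P between deviation and log2 length. The deviations of the high P and low P libraries correlated at 0.83 across genes, so plants or handling shared by both may be the source, and the 2 cannot be told apart because the labels do not say what a replicate number marks.

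The 6 libraries of a genotype make 10 splits, too few for a share under 0.05. The real split gave 10753 calls in EP1, 7589 in F2, 5701 in F160, 12703 in F142, 13872 in SF1, 8213 in SM1, 5611 in F7 and 49 in P415, and every other split of these genotypes gave 0, so 1 of 10 reached the real count; in P024 all 10 gave 0. In F160, P024 and P415, where same-numbered libraries correlated above 0.1, the other splits that parted all 3 such pairs also gave 0.

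For the joint model P labels were reassigned within genotypes in 40 draws, the real one included, with a faster dispersion setting that gave 11558 calls for the average response. Chance is argued against as the source of that whole count. Only 1 of 40 draws, the real one, reached it, and the highest other count was 52. Single calls are not covered. In these draws a genotype largely loses its response unless its real split is kept or mirrored, so they do not test equal responses. For the interaction they gave 13480 calls (1 of 40, highest other 6137), and against the other 8 genotypes the real count was reached by 4 of 40 in F142, by 11 of 40 in P024 and by 1 of 40 in the other 7. The 4 draws in F142 include the real one, and the others may hold its own response. Other splits of F142 gave 0 calls in its own fit.

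After these were seen, residuals around genotype means and 1 common low P effect were reassigned in 100 draws, which keep a shared response. The interaction had 13252 calls, reached by 1 of 100 draws, with a highest other of 9512. Against the other 8 genotypes 1 of 100 reached the real count in EP1 (1881, highest other 283), F2 (1665, 431), F160 (330, 18), F142 (1944, 1104), SF1 (2375, 1222), SM1 (2603, 1029) and F7 (10817, 9783), and 2 of 100 in P415 (917, 996). At most 2 of 100 draws reached each of these counts, which argues against chance as the source of the whole count. It does not cover single calls. Some draws gave many calls in F7 and more than the real count in P415. The residuals hold each genotype's own deviation, and a draw can restore or mirror its split by P level. Such draws do not have equal responses, so the highest counts do not measure false calls. The ranks were not adjusted for the number of comparisons, and the library labelled F7 low P 2 was kept in all draws. For P024, 40 of 100 reached 1709, with a highest of 10791, so chance is not excluded over all draws. Of these, 39 did not part all 3 pairs of same-numbered libraries; of the 38 draws that did, 1 reached 1709, the real one, with a highest other of 690. The pairing is read from the values and not from the labels, and not every P024 library correlated best with its own number, so P024 stays open. Draws with several times the real P024 count point to a structure among its libraries other than the P level.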

How the results depend on the processing

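The alternatives that leave out P024, F7 low P 2 or F7 high P 1 libraries together or from anything but the fit of their own genotype, and those of matK and the mitochondrial features, were chosen only after the results were seen. Under the alternatives tried, 37 counts of calls moved by over 1.5 times and 88 stayed within it, the mitochondrial features apart, whose 2 counts also moved (from 6 to 10 on average and from 0 to 1 in F7); another 11, of P024, were 0 as reported, in a comparison that recovered 0% of simulated 4-fold changes, and show no stability. For single genes, 47 alternatives for the 4 printed genes and matK kept direction and threshold; the other 3, all in the second count table alone, kept direction only. RLE scaling moved no count past 1.5 times.

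With changes of at least 2-fold the counts were 4243 in EP1, 4001 in F2, 2788 in F160, 5028 in F142, 5517 in SF1, 4509 in SM1, 2535 for the average response and 674 for genes called one way in at least 6 genotypes, in place of 1452; fewer genes pass by construction. In the joint model, whose pooled spread is wider than that of most single genotypes, they were 4533 in EP1, 4850 in F2, 2478 in F160, 6254 in F142, 6939 in SF1, 10739 in F7, 317 in P415, 47 in P024 and 916 for the shared genes. DESeq2 gave 1 in P024 and 323 in P415, and no filter 82 in P415; the cause was not tested. The second table alone gave 1167 for the average response and 748 for the interaction, and the first alone 17115 and 16776; the cause was not tested. Leaving out P024, F7 low P 2 and F7 high P 1 gave 14568 and 18400.

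With each library left out, counts ran from 8280 to 12334 in EP1, 4607 to 7936 in F2, 3333 to 5803 in F160, 10644 to 12064 in F142, 12124 to 12960 in SF1, 4826 to 8287 in SM1, 2567 to 8395 in F7, 1 to 62 in P415 and 0 to 0 in P024. With each replicate number left out they ran from 7738 to 9898 for the average response and from 4320 to 9440 for the interaction.

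The replicate block gave 5407 calls in F160, 0 in P024 (1532 at an unadjusted p under 0.05) and 49 in P415 (33 called in both fits), where the numbers pair the libraries by correlations over 0.1 (each library correlated best with its own number in F160, not in P024 or P415), and changed no other call by over 1.5 times. Elsewhere the block gave 9646 in EP1, 6945 in F2, 10132 in F142, 12864 in SF1, 5659 in SM1, 4129 in F7, 12917 for the average and 15481 for the interaction; of these genotypes each library correlated best with its own number in F2 alone. The gene list alternatives were not run, because no list could be filled. Depth limits matK, which was under 3 CPM in every library.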

Other observations

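The test of genotype pairs and the values below were chosen only after the results were seen.

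Non-coding RNA features, summed, were lower at low P in 7 of 9 genotypes, with a mean difference of -0.27 in log2(CPM + 0.5) (SD 0.41 over genotypes), a permutation p of 0.00085 and an adjusted p of 0.00255. Mitochondrial features other than rRNA were higher in 7 of 9, by 0.29 on average (SD 0.65), with a permutation p of 0.0211 and an adjusted p of 0.0422. All mitochondrial features together differed by -0.03 (higher in 5 of 9, permutation p 0.811, adjusted p 0.811) and rrn26 by -0.10 (higher in 5 of 9, permutation p 0.462, adjusted p 0.554), neither past the threshold. All 154 microRNA features were at 0 in every library. The mitochondrial rrn26 stood at 80.5 and 76.1 CPM in the P024 libraries numbered 3, against 215 to 406 CPM in the other P024 libraries.

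In P024, Zm00001d005742 was at 6.024, 11.03 and 0 CPM in the high P libraries 1, 2 and 3, and at 25.35, 4.695 and 66.25 CPM in the low P libraries 1, 2 and 3.

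Genotypes that differ in few on and off genes might respond to low P alike. Over 15 pairs of first-table genotypes the number of genes expressed in one and silent in the other and the correlation of their responses had a Pearson r of -0.259 (exact permutation p = 0.375 over 720 orders) and a Spearman rho of -0.258 (p = 0.361), so the hypothesis gained no support and stays open with 6 genotypes. F160, F142 and SF1 had the fewest such genes, at 46, 46 and 48 per pair, and correlations of 0.602, 0.661 and 0.724, while SF1 and SM1, with 146, had 0.812.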
